A study of Mus musculus with 4 samples.

How the data were processed

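RNA sequencing was carried out on mouse pancreatic islets (C57BL/6 strain), with 1 library in each of 4 groups: control islets, islets labelled as a knockout of IMP2, RNA recovered from wild-type islets by immunoprecipitation of IMP2 (RNA immunoprecipitation, RIP), and a library labelled IgG, the usual antibody control of such an experiment. IMP2 is the RNA-binding protein encoded by Igf2bp2. Per the labels' protocols, islets were flash frozen, RNA was extracted with Trizol, and Illumina libraries were sequenced. The control and knockout groups were taken from the genotype given for each sample (control, and Rip2;IMP2, which the series title calls an islet-specific knockout), and the RIP and IgG groups from the sample titles.

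The deposited files hold whole-number counts of reads per gene, 1 file per library, each with 43629 Ensembl mouse genes and 5 closing entries that name no gene. Per the submitters' processing notes, the tools were STAR, an aligner, and HTSeq, a read counter, with the mm10 mouse genome build. Tool versions, the annotation release and the strand option of the counting were not given in the sources used here, so reads of a gene and of an antisense or overlapping gene may not be separable. The 5 closing entries (reads in no feature, in more than 1 feature, of low quality, not aligned, or aligned more than once) held 50.8% of the deposited total in control islets, 50.3% in the labelled knockout, 72.4% in the RIP and 70.5% in the IgG library. They stayed out of library sizes and ratios. Reads that align more than once are not assigned to a gene by such counting, so genes with near-identical copies are undercounted: Gapdh stood at 12.0 CPM in control islets, where CPM is a count scaled to a common total of gene counts. Ribosomal protein genes, immunoglobulin variable segments, Ins1 and Ins2, Gapdh and Gm42418, which lies over ribosomal RNA sequence, are uncertain for this reason. All 37 genes of the mitochondrial genome held 0 counts in all 4 libraries, so the list of mitochondrial-encoded genes has no result.

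Gene names, gene types and coordinates came from GENCODE M21 (GRCm38, the same assembly as mm10), which matched 42548 of the 43629 identifiers. The 1081 others kept their identifiers. CPM values were computed here over the gene counts of each library. Each pair of libraries was scaled by the trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. A gene was measured in a comparison when its mean CPM over both libraries was at least 1. The ratio of the scaled levels has an exact 95% interval (Clopper-Pearson, on the count of 1 library out of the sum of both). A gene was called higher or lower when the interval excluded 1 and the ratio was at least 1.5-fold for the labelled knockout over control, or 2-fold for RIP comparisons. For list medians, 0.5 counts were added before the log2. A fold against a library at 0 counts is given as a bound computed against 3 counts in that library, which is 0.114 CPM in control islets, 0.124 in the labelled knockout, 0.498 in the RIP and 0.227 in the IgG library. Sequencing reads without molecular identifiers are not independent molecules, so all intervals on ratios and all floors cover counting error only. For the RIP and IgG libraries they are likely too narrow by more. Reads per molecule, estimated as the median count of genes with over 5 counts and at 0 in both islet libraries, were 18 and 21. Limits on estimated molecules divide the counts by these. Genes of another tissue can be among those used and hold several molecules each, so these estimates are rough and may be too high. With 1 library per group there is no replicate check of any difference, no p-value is given, and each interval compares 2 libraries, not 2 conditions. Other steps used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.

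The comparisons, the limits, 30 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The named genes are Igf2bp2, Igf2bp1, Igf2bp3 and Pdx1, the 12 genes called higher and the 12 called lower whose interval bound nearest to 1 lay farthest from 1 at a mean CPM of at least 5 (without predicted genes, RIKEN clones and pseudogenes by symbol), and members of the lists as examples, mainly those with extreme ratios and the most abundant markers of other cell types. The lists cover Igf2bp2 and its paralogs; beta cell identity, stimulus-secretion coupling, prohormone processing and granules, and genes disallowed in beta cells; markers of alpha cells, of delta, PP and epsilon cells, and of acinar, ductal, endothelial, mesenchymal and immune cells, and of Schwann cells, adipocytes and blood. They also cover the unfolded protein response, S and G2/M phase, G1 cyclins and CDK inhibitors, insulin and PI3K-AKT signalling, IMP2 targets named in earlier work, nuclear OXPHOS subunits, mitochondrial-encoded genes, ribosomal proteins, replication-dependent histones, small and structured noncoding RNA, nuclear long noncoding RNA, immediate early and heat shock genes, interferon response, hypoxia and glycolysis, cholesterol and lipid synthesis, m6A machinery and sex-linked genes. A further 7 lists were written after the values were seen: brown adipocyte, evening-phase clock, morning-phase clock, B cell, T cell, macrophage and lymph node stroma. For each list with at least 3 measured members, the median log2 ratio is given with its percentile among 10000 random lists of the same size matched on 10 bins of mean expression, as a description of these libraries. A percentile under 2.5 or over 97.5 is described as standing apart.

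Alternatives were library totals, DESeq2 1.42.0 size factors, totals without acinar and hormone genes, a minimum of 5 CPM or no filter, other fold limits, an assumed variation of 0.2 per library, protein-coding genes only, other matching, means over members, and control islets in place of the IgG library. Chosen after seeing the data were both islet libraries summed as denominator, intervals on estimated molecules, and leaving out lymphoid and immune genes. The RIP over IgG ratio depends on its scaling: TMM shifted all genes by -0.69 on the log2 scale relative to library totals, which moved the median of all measured genes from 1.13 to 0.45.

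The calls were tested on simulated data with 200 changed genes. For the labelled knockout over control (15735 genes), 54% of genes changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold or to 0.25 were called, along with 0.406% of unchanged genes. With a simulated variation of 0.2 between libraries, which 1 library per group cannot measure, 17.4% of unchanged genes were called. For RIP over IgG (14822 genes), 4% of genes changed 1.5-fold, 38% of those changed 2-fold, 100% of those changed 4-fold and 92% of those changed to 0.25 were called, with 0.595% of unchanged genes, and with 4.07% of them at a variation of 0.2. Of 400 random lists of 20 genes without a shift, 5.25% stood apart for the labelled knockout over control and 4.50% for RIP over IgG. All lists shifted by 0.5 log2 units did in both. These simulated libraries differed by counting error only, and real genes vary far more. In RIP over IgG, S and G2/M phase genes had a median of 3.81 against 1.69 in random lists, at percentile 88.5. A list that does not stand apart there may therefore still be shifted by more than 0.5.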

Results

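The series measured RNA in mouse pancreatic islets, the hormone-secreting cell clusters of the pancreas, to ask which RNAs differ in level without IMP2 and which are recovered with it. IMP2 belongs to a family of RNA-binding proteins that regulate the stability, transport and translation of mRNA. There were 4 libraries, 1 per group. Control islets gave 26350813 gene counts over 24350 detected genes, and islets labelled as the IMP2 knockout gave 24275628 over 24412. The IMP2 RIP gave 6025594 over 15380, and the library labelled IgG gave 13195732 over 14105. Ins1 and Ins2 together made up 29.9% of gene counts in control islets, 32.1% in the labelled knockout, 22.5% in the RIP and 0.0931% in the IgG library. Gm42418, which overlaps ribosomal RNA, made up 1.53%, 1.70%, 17.6% and 3.57% in the same order.

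Igf2bp2, which encodes IMP2 (ENSMUSG00000033581, mm10 chromosome 16, 22059009 to 22163299, minus strand), was not lower in the library labelled knockout. It had 255 counts in control islets (9.68 CPM), 222 in the labelled knockout (9.14 CPM), 186 in the RIP (30.9 CPM) and 458 in the IgG library (34.7 CPM). Its ratio of labelled knockout over control was 0.978 (95% interval 0.813 to 1.17). The labels give the genotype as Rip2;IMP2 and call the knockout specific to islets. Rip2 is a common name for an insulin gene promoter that is active in beta cells, so other cells in the islet preparation may keep the intact gene. A count over the whole gene also does not check a deletion of part of it, and which exons were targeted was not given in the sources used here. The library is therefore called the library labelled knockout, and every direction below is drawn between these libraries without a check of the label. The paralog Igf2bp1 (ENSMUSG00000013415, chromosome 11, 95957163 to 96005940, minus strand) had 9, 32, 736 and 523 counts in the same order of libraries. Igf2bp3 (ENSMUSG00000029814, chromosome 6, 49085223 to 49214957, minus strand) had 32, 10, 26 and 69. Of these 3 genes only Igf2bp2 reached 1 CPM on average over both islet libraries. The ratio of labelled knockout over control was 3.99 for Igf2bp1 (1.86 to 9.51) and 0.351 for Igf2bp3 (0.154 to 0.732), both below the expression limit for a call.

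**Figure D1:**
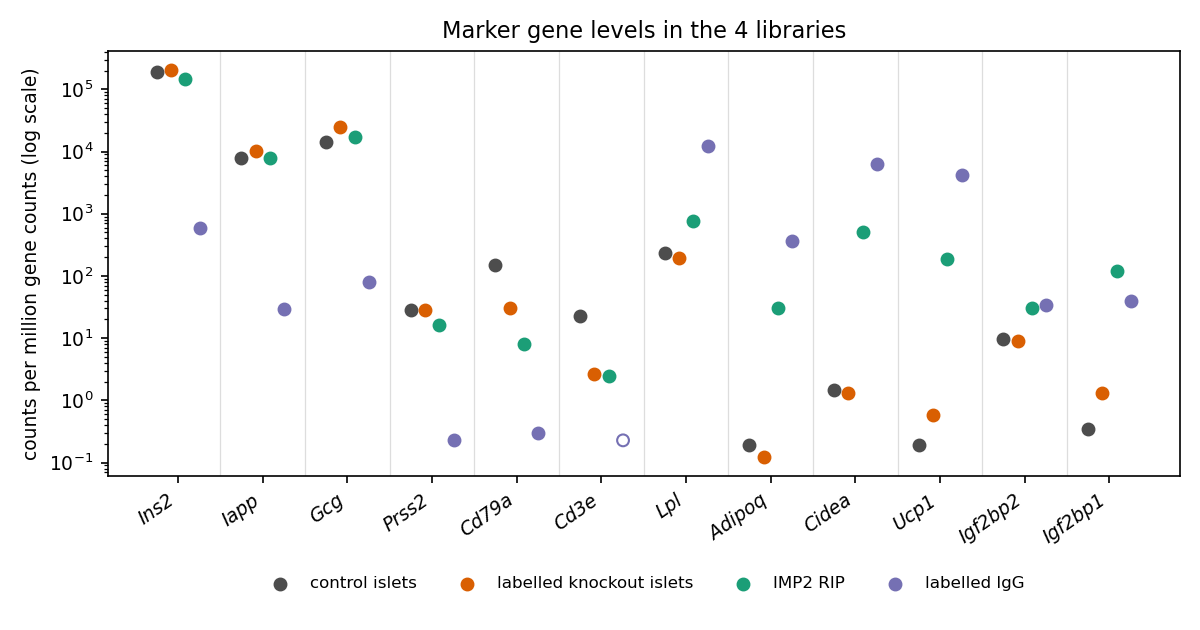
Levels of 12 marker genes in the 4 libraries, 1 point per library, in counts scaled to a common total (CPM, log axis), with an open circle at the level of 3 counts where a library had 0. Islet hormone genes sit high in control, labelled knockout and RIP libraries and low in the IgG library, where the fat genes Lpl, Adipoq, Cidea and Ucp1 sit highest.

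The library labelled knockout held far less RNA of lymphocytes and of dividing cells than control islets, and moderately more RNA of beta and alpha cells. Cd3e, a subunit of the T cell receptor complex, was 8.22-fold lower. Mafa, a transcription factor of mature beta cells, was 1.86-fold higher, and Gcg, which encodes glucagon, was 1.81-fold higher, at 14006 CPM in control islets and 24536 in the labelled knockout. Of 15735 measured genes, 962 were called higher and 2416 lower in the library labelled knockout, 21.5% in all.

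Genes of beta cell identity were shifted upward in the library labelled knockout. All 22 were measured, 4 were called higher and 0 lower, and their median log2 ratio of 0.39 lay above all 10000 matched random lists. The called genes included the transcription factors Mafa, Neurod1 at 1.58-fold and Nkx2-2 at 1.54-fold. Pdx1, a transcription factor of pancreas development and beta cells (ENSMUSG00000029644, chromosome 5, 147269959 to 147275848, plus strand), had a ratio of 1.45 (1.38 to 1.53), under the 1.5-fold limit. Ins1 and Ins2, which share reads, had ratios of 1.13 and 1.10. Genes of stimulus-secretion coupling had a median of 0.28 over 27 genes (percentile 99.96). Within that list the exocytosis genes Rab3a (1.57-fold) and Snap25 (1.51-fold) were called higher, and the IP3 receptor gene Itpr3 was called 1.53-fold lower. Prohormone processing and granule genes had a median of 0.31 over 15 genes (percentile 99.38) with 0 called either way. Chgb, which encodes a granin, had a ratio of 1.33.

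Alpha cell genes were shifted further, with 4 of 9 called higher and a median of 0.47 (percentile 99.97). Besides Gcg, these included Irx1 at 1.83-fold and Irx2 at 1.64-fold. Delta, PP and epsilon cell genes did not stand apart, with 0 of 6 called and a median of -0.20 (percentile 9.42), with Sst, which encodes somatostatin, at a ratio of 1.14 and Ppy, which encodes pancreatic polypeptide, at 0.734 (6370 CPM in control islets and 4518 in the labelled knockout). The immune share of the RNA, described below for the same 2 libraries, moved against these islet lists.

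Immune genes had 14 of 20 measured members called lower in the library labelled knockout and 0 higher, with a median log2 ratio of -1.54, below all 10000 random lists. Ptprc, the pan-leukocyte marker CD45, was 6.11-fold lower, Ms4a1 (CD20) 5.28-fold and Cd79a 4.91-fold. C1qa and Adgre1, markers of macrophages, were not called, with ratios of 1.07 and 1.22. In lists written after the values were seen, all 12 B cell genes and all 12 T cell genes were called lower, with medians of -2.30 and -3.00, both below all random lists. Lymph node stroma genes had 4 of 7 called lower with a median of -2.82, also below all random lists, led by Glycam1, a mucin of lymph node vessels, at 15.4-fold and Ccl19 at 12.8-fold. Macrophage genes had 1 of 12 called higher (Mrc1, 1.77-fold) and 4 lower, with a median of -0.15 (percentile 13.9). Lyz2 was the member with the lowest ratio, 3.58-fold lower. Immunoglobulin genes held 0.376% of gene counts in control islets and 0.0936% in the labelled knockout.

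Genes of S and G2/M phase had 26 of 28 members called lower in the library labelled knockout and 0 higher, with a median of -1.10, below all random lists. The replication licensing genes Mcm3 and Mcm4 were 3.92-fold and 3.79-fold lower, Rrm2, a subunit of ribonucleotide reductase, 3.76-fold, and Top2a 2.84-fold. G1 cyclins and CDK inhibitors did not move as a group, with a median of 0.00 over 13 genes (percentile 49.9), and Cdk6 and Ccnd3 were called lower at 2.21-fold and 1.67-fold. Genes disallowed in beta cells had 11 of 16 called lower, a median of -0.68 and 0 random lists as low. Members called lower included Arap2 at 3.20-fold, the hexokinase gene Hk2 at 3.07-fold and the lactate dehydrogenase gene Ldha at 2.47-fold. Ribosomal protein genes, whose reads are shared with pseudogenes, had a median of -0.34 over 85 genes, below all random lists, with 9 called lower. The interferon response list had a median of -0.38 over 16 genes (percentile 0.84), with Gbp2 at 2.65-fold and Gbp3 at 1.84-fold lower, but did not stand apart by the mean of its members (percentile 13.5). The lymphocyte genes moved the same way as each of these 5 lists except G1 cyclins and CDK inhibitors.

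**Figure D2:**
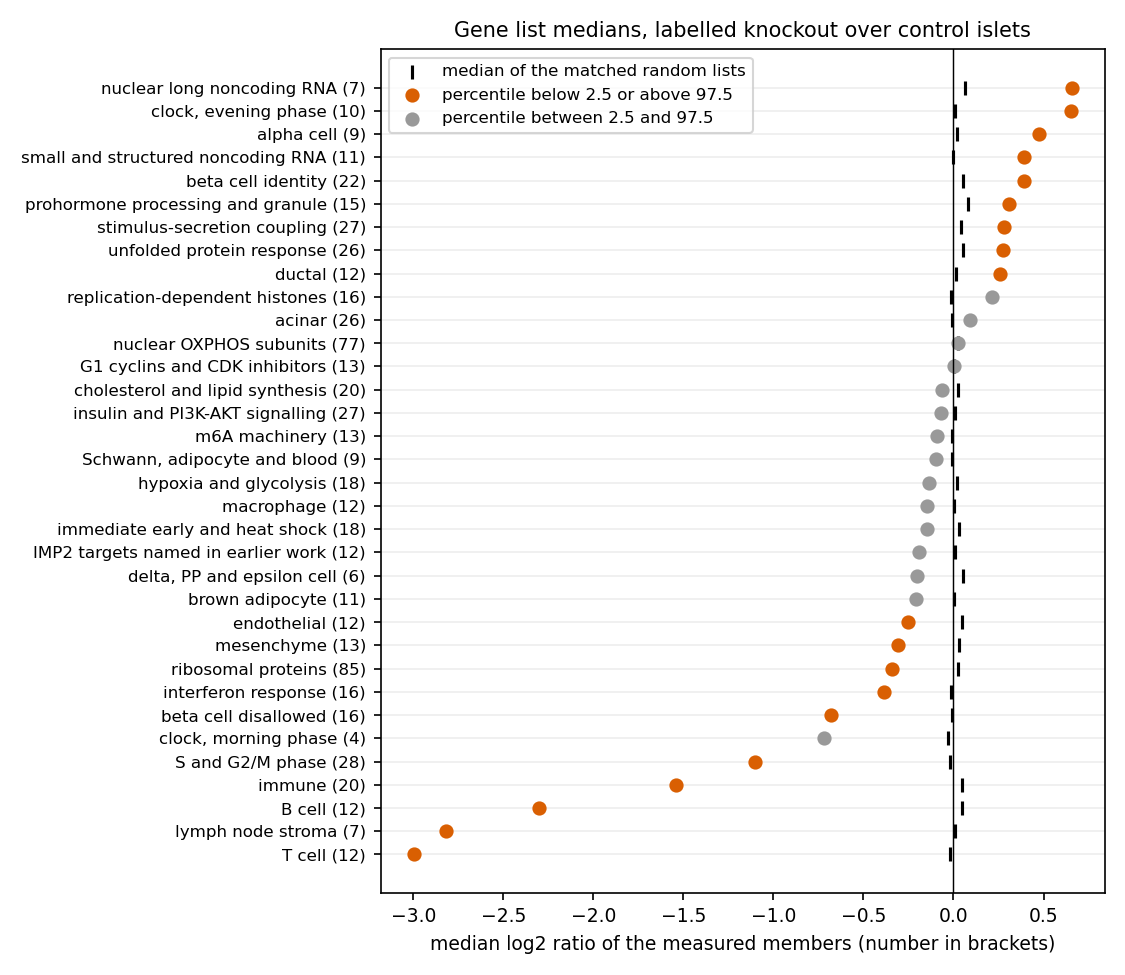
Median log2 ratio, labelled knockout over control islets, of each gene list with its number of measured members in brackets, next to the median of its matched random lists (bars). T cell, lymph node stroma, B cell and immune lists lie lowest, at -3.00, -2.82, -2.30 and -1.54, and nuclear long noncoding RNA lies highest at 0.66.

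Among other lists, the unfolded protein response was shifted upward in the library labelled knockout, with 3 of 26 genes called higher and a median of 0.28 (percentile 99.88), about as large as those of the secretory lists and with the immune share likewise moving against it. Dnajb9, a chaperone of the endoplasmic reticulum, was 2.28-fold higher, Manf 1.85-fold and Atf3 1.61-fold. Nuclear long noncoding RNA had 5 of 7 called higher and a median of 0.66, above all random lists, with Kcnq1ot1 at 1.73-fold, Miat at 1.65-fold, Neat1 at 1.58-fold, and Snhg11 at 136.5 CPM against 70.7 in control islets. Ductal genes had a median of 0.26 over 12 genes (percentile 98.5), with Cftr, a chloride channel, at 1.81-fold and Krt18 at 1.51-fold, but did not stand apart by their mean (96.8) or at a minimum of 5 CPM. Small and structured noncoding RNA had a median of 0.39 over 11 genes (percentile 98.6) but a mean of -0.11, with 1 called higher and 2 lower. Endothelial genes had a median of -0.25 over 12 genes (percentile 1.34), with Pecam1 called 1.79-fold lower, and mesenchymal genes a median of -0.31 over 13 genes (percentile 0.74) with 0 called. By the mean neither list stood apart (percentiles 12.2 and 8.17). Acinar genes did not stand apart, with a median of 0.09 over 26 genes (percentile 87.1). Their 4 members called higher included Bhlha15, a transcription factor of secretory cells, and their 5 called lower included Reg1 at 2.01-fold.

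The other lists described here did not stand apart from random lists. IMP2 targets named in earlier work had 12 measured members and a median of -0.19 (percentile 6.26), with Myc 1.82-fold and Ccnd3 1.67-fold lower. Insulin and PI3K-AKT signalling had a median of -0.07 over 27 genes (percentile 17.2), with Foxo1 alone called, 1.69-fold lower. Nuclear OXPHOS subunits had 0 of 77 called and a median of 0.03 (percentile 48.6). Medians were -0.15 for immediate early and heat shock genes (percentile 5.22), -0.13 for hypoxia and glycolysis (9.01), -0.06 for cholesterol and lipid synthesis (17.7) and -0.09 for m6A machinery (22.9). Hspa1b, an inducible heat shock gene, was 3.67-fold lower and Fosb 2.97-fold lower, while Ier3 was 1.68-fold higher. Scd1, a fatty acid desaturase, was 3.45-fold lower. Medians were 0.22 for replication-dependent histones (percentile 94.1), -0.10 for Schwann, adipocyte and blood markers (29.6) and -0.21 for the later brown adipocyte list (13.0). Of the sex-linked genes only Xist was measured, at 599.8 CPM in control islets and 748.3 in the labelled knockout. Genes of the Y chromosome summed to 7.48 CPM in control islets and 0.824 in the labelled knockout. The mice of these libraries may thus have differed in sex, which cannot be told apart from the label in this comparison.

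The 12 genes standing farthest above 1 in the library labelled knockout were led by S100a9, a neutrophil calcium-binding protein, with 335 counts against 3 in control islets (125.4-fold, 42.5 to 611). They included 3 immunoglobulin variable segments, among them Igkv12-89 (9.33-fold) and Ighv11-2 (5.04-fold), whose reads can be split between near-identical segments. The others were the clock gene Per3 at 2.87-fold (2.56 to 3.23), the prostacyclin synthase gene Ptgis at 3.06-fold, Mapk4 at 2.98-fold, Fcna at 2.78-fold, Adgrd1 at 2.77-fold, Olfm4 at 2.59-fold, Bhlha15 at 2.35-fold and Dnajb9. The 12 standing farthest below 1 held 8 immunoglobulin genes, among them Ighg1 at 31.4-fold (23.2 to 43.6), Ighg3 at 31.0-fold, Ighg2b at 19.8-fold, Ighv1-50 at 81.6-fold and Ighv1-26 at 44.8-fold lower. Also among them were the variable segments Igkv5-48 at 36.0-fold and Igkv5-39 at 23.7-fold. Alpi, an intestinal alkaline phosphatase, had 306 counts in control islets and 1 in the labelled knockout (272.5-fold lower, 48.5 to 10799). S100g had 335 and 2 counts (149.2-fold lower), Apoa1, the main apolipoprotein of HDL, was 27.8-fold lower (16.7 to 50.2), and Dsc3, a desmosomal cadherin, was 25.2-fold lower.

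These calls rest on counting error alone. An assumed variation of 0.2 per library left 264 genes higher and 1586 lower, and simulated data with that variation called 17.4% of unchanged genes against the observed 21.5%.

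The comparison of RIP with IgG asks which RNAs were recovered with IMP2 beyond those recovered with a control antibody. Islet genes were higher in the RIP and genes of brown fat were higher in the library labelled IgG, by large factors in both directions. Iapp, which encodes islet amyloid polypeptide, was 167.0-fold higher in the RIP (151.2 to 184.9). Ucp1, the uncoupling protein of brown fat, stood at 4121 CPM in the IgG library, 186.4 in the RIP and 0.190 in control islets. Of 14822 measured genes, 6409 were called higher and 4513 lower under TMM scaling, 73.7% in all. The split was 7670 and 3387 under library totals, and 8542 and 2805 under totals without acinar and hormone genes. Among the abundant genes of the IgG library were the lipid metabolism genes Scd1 at 34177 CPM and Lpl at 12376, and Car3, a carbonic anhydrase, at 12496, and it held 4431 CPM of Fabp4 and 358.1 of Adipoq.

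Each of the 22 beta cell identity genes was called higher in the RIP than in the IgG library, with a median log2 ratio of 7.24 (7.07 with genes at 0 set at their bound), above all 10000 matched random lists. Stimulus-secretion coupling genes (24 of 27 higher, 2 lower, median 5.82, 5.32 at the bound) and granule genes (15 of 15 higher, median 6.78) also lay above all random lists. Alpha cell genes had 8 of 9 higher (median 5.35, 5.18 at the bound, percentile 99.85). Delta, PP and epsilon cell genes had 4 of 6 higher, with a median of 6.42, or 5.11 at the bound (percentile 99.89). Acinar genes had 20 of 20 higher (median 6.33, 6.14 at the bound, percentile 99.99) and ductal genes 9 of 11 (median 4.94, percentile 99.67). Unfolded protein response genes had 14 of 26 higher and 0 lower, with a median of 1.41 (percentile 99.99). Hyou1 was 11.4-fold and Pdia4 6.48-fold higher.

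In the other direction, 78 of 79 nuclear OXPHOS subunits were called lower in the RIP than in the IgG library and 0 higher, with a median of -3.84, below all random lists. Atp5k, a subunit of ATP synthase, was 26.9-fold lower and Cox6a1, a subunit of cytochrome c oxidase, 26.8-fold. Schwann, adipocyte and blood markers had 8 of 11 lower and a median of -4.31, below all random lists, with Hba-a2 102.5-fold lower and Adipoq 19.1-fold. The brown adipocyte list, written after the values were seen, had 21 of 23 lower and a median of -4.32, again below all random lists. Ribosomal proteins had 59 of 81 lower (median -1.97, percentile 0.03) and hypoxia and glycolysis genes 13 of 17 lower (median -2.51, percentile 2.12, or 6.17 at a minimum of 5 CPM and 8.43 with 20 expression bins), with Tpi1 24.9-fold and Ldha 21.3-fold lower. Of 4 sex-linked genes Xist was 191.8-fold higher and 3 Y genes were lower, with a median of -5.0, or -3.70 at the bound (percentile 0.18, or 5.76 at a minimum of 5 CPM and 3.08 by the mean). Y genes summed to 59.9 CPM in the IgG library and 9.79 in the RIP.

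IMP2 targets named in earlier work were called higher in the RIP than in the IgG library for 8 of 13 genes and lower for 4, with a median of 1.18 (percentile 92.5). Pdx1 was 61.4-fold higher (30.8 to 143.4, or at least 4.75 on estimated molecules), Ctnnb1 20.3-fold and Ccnd1 9.09-fold, while Ucp1 was 35.6-fold and Igf2 14.1-fold lower. Igf2bp2 was 1.81-fold lower (ratio 0.553, 0.464 to 0.657) and Igf2bp1 1.92-fold higher (1.71 to 2.15), and Igf2bp3 had a ratio of 0.513 (0.314 to 0.816), all within the 2-fold limit. On estimated molecules the intervals of Igf2bp2 (0.236 to 1.21) and Igf2bp3 (0.0252 to 4.84) span 1. Under totals without acinar and hormone genes the log2 ratios of these 3 genes were 0.26, 2.05 and 0.17, so their direction or call rests on the scaling. Of other lists, immune genes (13 of 20 higher, median 1.73, percentile 98.2), nuclear long noncoding RNA (4 of 7, median 2.15, percentile 99.4) and immediate early genes (10 of 17, median 2.5, percentile 99.5) stood apart upward, though the last 2 did not by the mean of their members (percentiles 95.2 and 80.4). The later B cell list did so too (9 of 10, median 4.24, 3.76 at the bound, percentile 98.0).

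Of the lists that did not stand apart in RIP over IgG, medians were 3.81 for S and G2/M phase genes (3.62 at the bound, percentile 88.5), 0.78 for insulin and PI3K-AKT signalling (95.8), -0.01 for G1 cyclins and CDK inhibitors (30.9) and 0.18 for histones (25.7). Medians of further lists were 4.02 for small noncoding RNA (2.97 at the bound, percentile 78.6), -1.24 for endothelial genes (22.5), -0.67 for mesenchymal genes (51.8), -1.09 for disallowed genes (14.4), -0.36 for interferon response (11.4), -1.22 for cholesterol and lipid synthesis (22.8) and -0.32 for m6A machinery (21.7). The target and its paralogs had a median of -0.85 (percentile 26.4). Among later lists, medians were 0.80 for the evening clock (81.9), -0.30 for the morning clock (16.3), 4.02 for T cell genes (2.87 at the bound, 50.8), 1.74 for macrophage genes (73.0) and 5.25 for lymph node stroma (4.43 at the bound, 86.4).

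The genes farthest above 1 in RIP over IgG were Phactr1, a regulator of actin and protein phosphatase 1, with 4264 counts against 2 (2903-fold, 803 to 23977), Tm4sf4 (1488-fold), Rapgef4, a cAMP sensor of beta cell exocytosis (1475-fold), and Neurod1 (987-fold), which had 1 IgG count each apart from Phactr1. The others were Spc25 (683-fold), Snap25 (473-fold), Wnt4 (359-fold), G6pc2, an islet glucose-6-phosphatase (282.4-fold, 214 to 381), Chgb (195.5-fold) and Iapp. Efcc1 and Sez6l had 0 IgG counts against 701 and 484 in the RIP. If the rough estimates of 18 reads per molecule in the RIP and 21 in the IgG library hold, limits from reads are far too high. The IgG estimate was not checked further. On estimated molecules the lower limits were 70.6-fold for Phactr1, 18.0-fold for Rapgef4, 11.7-fold for Efcc1 and 7.94-fold for Sez6l. Farthest below 1, the plasma protein genes Ahsg, Afp and Apoa1 had 0 RIP counts and 1255, 1072 and 720 in the IgG library, and were at least 13.5-fold, 11.4-fold and 7.54-fold lower on estimated molecules. Alb was 283.5-fold lower, or at least 24.3-fold on molecules. Cyp2b10, Srr, Sspn and Mycl, also at 0, were at least 7.41-fold, 5.44-fold, 5.41-fold and 5.37-fold lower on molecules. With 1 RIP count each, Fabp3, a fatty acid carrier of heart and brown fat, was at least 12.4-fold lower on molecules, Unc45b 8.18-fold, Cldn15 7.30-fold and Hrct1 7.18-fold.

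These ratios compare 2 libraries whose RNA differs in kind, so a high ratio over IgG also marks a gene that islets express and the IgG library lacks. With intervals on estimated molecules, 2315 genes were higher and 2822 lower.

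Against control islets, the RIP library held islet genes near their islet level and stood out for fat genes, some small noncoding RNAs and the Igf2bp family. Of 15968 measured genes, 2723 were called higher and 3835 lower at 2-fold, or 1394 and 964 with intervals on estimated molecules. Beta cell identity genes had a median log2 ratio of 0.09 (percentile 75.8) with Neurod1 alone called, just past the 2-fold limit under TMM and 1.63-fold, without a call, under library totals, and Pdx1 had a ratio of 0.766 (0.684 to 0.856). Igf2bp2, Igf2bp1 and Igf2bp3 were all called higher, at 3.92-fold (3.23 to 4.75), 439-fold (230.2 to 965) and 4.36-fold (2.5 to 7.56), with a median of 2.13 (percentile 99.22). On estimated molecules the intervals were 1.88 to 7.26 for Igf2bp2, 210.3 to 1028 for Igf2bp1 and 0.280 to 20.6 for Igf2bp3, which spans 1. Apart from Igf2bp1, the 12 genes farthest above 1 were mainly genes of fat cells, such as Ucp1 (1207-fold), Cox8b (933-fold), Adig (653-fold), Cidea (436-fold), Car3 (392-fold) and Cfd (283-fold), which were higher still in the IgG library. This ratio shares its control library with the ratio of labelled knockout over control, so part of any likeness between them may come from that library.

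Small and structured noncoding RNA had 14 of 21 members called higher in the RIP than in control islets and a median of 2.80 (percentile 99.98), with Snord17 146.1-fold and Rnu3a 90.3-fold higher. Only these 21 of 170 genes were measured, with median levels of 0.569 CPM in control islets and 3.98 in the RIP. Most thus passed the limit of 1 CPM only through their RIP level, where higher was the only possible direction. The list result rests on reads, without limits on estimated molecules. Nuclear OXPHOS subunits had 42 of 78 higher and a median of 1.15, above all random lists, but their median level was 946 CPM in the IgG library against 114.4 in the RIP and 66.3 in control islets. A small share of the fat RNA of the IgG library would be enough for this rise, so it is not shown to be recovery with IMP2. The m6A machinery, which installs, removes and reads N6-methyladenosine, had 7 of 13 lower and a median of -1.08 (percentile 0.08), with Fto 6.34-fold, Mettl3 5.77-fold and Mettl14 5.21-fold lower. These folds rest on reads, and no limits on estimated molecules were computed for them. Immune genes had 16 of 20 lower (median -2.01) and S and G2/M genes 15 of 28 lower (median -1.09, percentile 0.02). Both lists were also lower in the labelled knockout than in control islets (medians -1.54 and -1.10). These ratios may therefore reflect the control library and not the RIP. Cr2, a complement receptor of B cells, had 1 RIP count and Ikzf3 had 0, and they were at least 6.49-fold and 6.02-fold lower on estimated molecules. Genes at a low level in control islets were often at 0 in the RIP. Of 2015 genes at 5 to 10 CPM in control islets, 18.7% had 0 RIP counts, against 0.298% in the labelled knockout thinned to the RIP total.

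**Figure D3:**
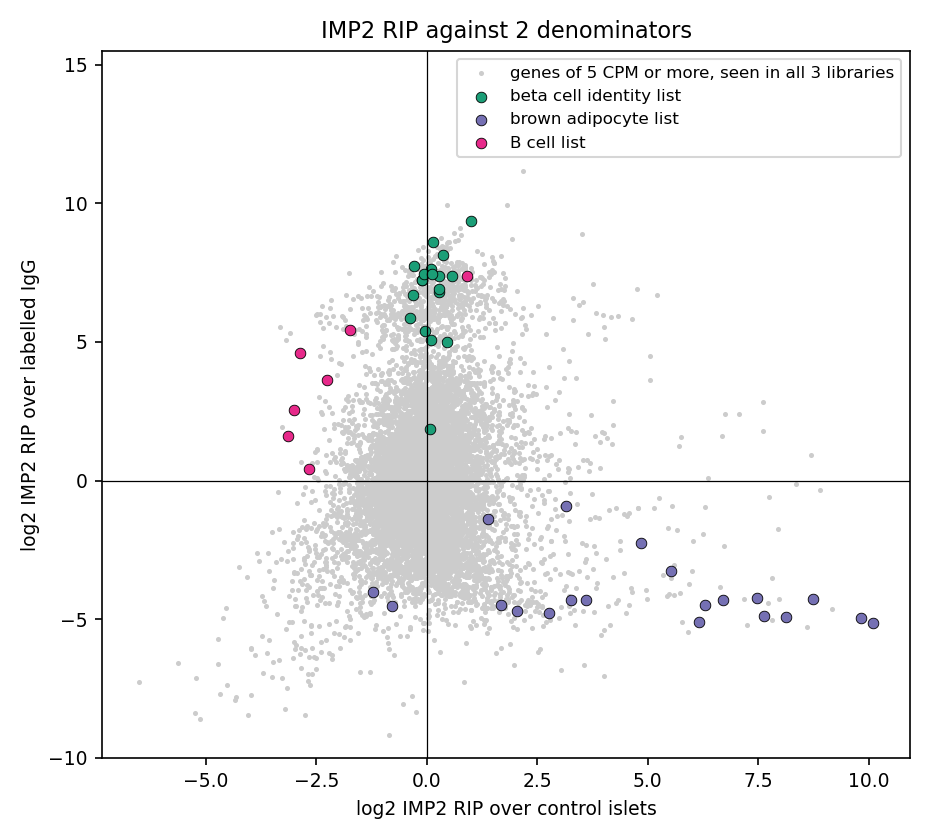
Log2 ratio of RIP over control islets (horizontal) and of RIP over IgG (vertical) for genes of at least 5 CPM that were seen in all 3 libraries, 1 point per gene. Beta cell identity genes lie high over IgG and near 0 over control islets (medians of the 19 plotted, 7.24 and 0.10), while brown adipocyte genes lie low over IgG and high over control islets (medians of the 20 plotted, -4.41 and 5.19).

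**Figure D4:**
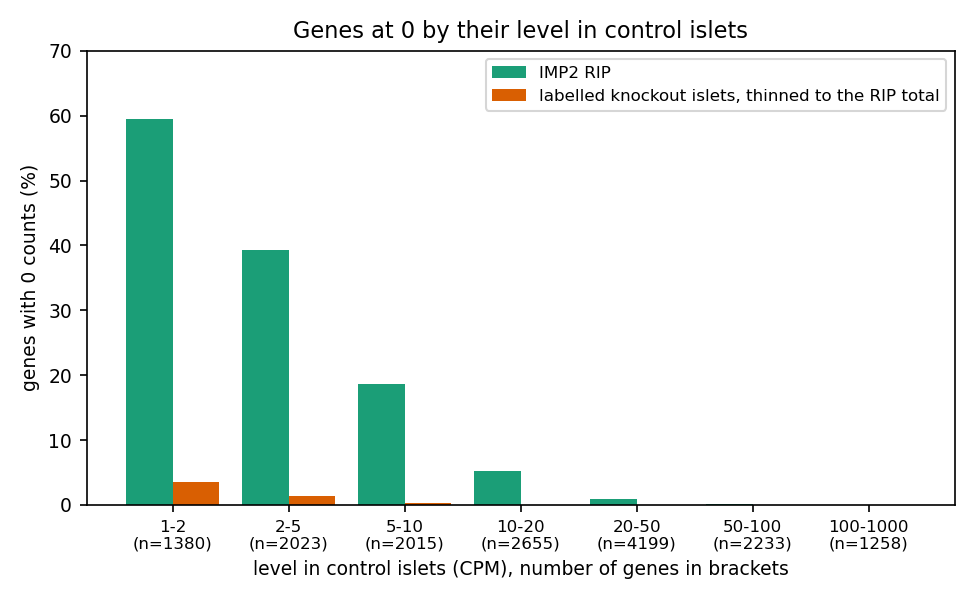
Percent of genes with 0 counts, by their level in control islets in CPM, in the RIP and in the labelled knockout thinned to the RIP total, with the number of genes under each pair of bars. At 1 to 2 CPM, 59.4% of 1380 genes were at 0 in the RIP and 3.55% in the thinned labelled knockout.

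The last comparison asks whether RNAs recovered with IMP2 differed in level in the library labelled knockout. The 4901 genes whose RIP over IgG interval lay wholly above 2-fold had a median log2 ratio of labelled knockout over control of 0.11, against 0.00 in matched random lists (above all 10000 lists). This set holds the islet genes that the IgG library lacks, such as Chgb and Snap25, and the islet lists were shifted upward as a whole. The 988 genes whose interval over both islet libraries lay above 2-fold had a similar median of 0.11, against -0.01 in random lists (above all of them). This set can hold fat RNA shared with the IgG library. In that ratio 43 of 78 nuclear OXPHOS subunits and 21 of 23 brown adipocyte genes were called higher. The set also rests on intervals on reads, and the islet libraries enter both ratios, so it is not separate support. In reverse, 679 genes called higher in the labelled knockout had a median log2 RIP over IgG of 4.35, above all random lists, whose median was 0.85. The 1670 genes called lower had a median of 0.94 (percentile 50.4), and this value depends on the minimum expression, the fold limit and the denominator.

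Among 13473 genes measured in both ratios, 487 were called higher in the labelled knockout and higher in RIP over IgG, where independent calls would give 282.7, and 99 were higher and then lower, against 203.3. Of genes lower in the labelled knockout, 827 were higher in RIP over IgG, against 695.4, and 436 were lower, against 500. With both islet libraries as denominator, which enter both ratios, and 14832 genes, the count higher in both held at 191 against 92.2. The other 3 turned, at 213 against 197.1 for genes higher and then lower, 167 against 238.1 for lower and then higher, and 1108 against 508.6 for lower in both. The 843 genes higher in the labelled knockout had a median of 0.10 over both islet libraries, against -0.10 in random lists. Between unchanged simulated libraries, a median of 42.5 genes called higher gave 0.07, and genes called lower gave 0.03. Those libraries hold no true difference between the islet libraries. They therefore cannot show how much of the observed 0.10 comes from sharing them. The observed value is not shown to reflect recovery with IMP2. In the overlaps with RIP over IgG, Dnajb9 and Mafa were among the genes higher in both, and Scd1 and Ldha among those lower in both. The ratios over IgG share no library with the labelled knockout over control, but both follow which cell types each library holds, and the label of the knockout library was not checked by Igf2bp2.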

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

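The tests of fat RNA in the IgG library, of lymphocyte genes in the labelled knockout and of genes at 0 in the RIP were chosen only after the results were seen.

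Reads outside annotated features made up a larger share of the deposited total in the other 3 libraries than in control islets (16.2%), at 17.6% in the labelled knockout, 25.7% in the RIP and 18.1% in the IgG library. Reads overlapping more than 1 feature made up 3.89% in control islets, 4.26% in the labelled knockout, 10.7% in the RIP and 4.29% in the IgG library. Alignments to more than 1 place made up 30.7% in control islets, 36.0% in the RIP and 48.2% in the IgG library. These reads enter no comparison.

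Brown fat genes were abundant in the library labelled IgG. Unselective recovery of islet RNA is argued against by the beta cell identity list, whose median log2 CPM ratio of IgG over control islets was -8.04 over 22 genes (interquartile range -8.49 to -7.25). A candidate source is RNA of brown fat or a like tissue in place of islet RNA, since nuclear OXPHOS subunits, fixed as a list beforehand, had a median ratio of 3.85 over 80 genes (interquartile range 2.71 to 4.97), and Adipoq, Plin1 and Fabp4 were all higher. The same RNA may lie in the RIP library at a small share, because 132 genes above 100 CPM in IgG and 30 times control islets had a median RIP level of 7.08% of the IgG level (interquartile range 5.14% to 8.37%), with 3 genes above 20%. Igf2bp1, which lies below that limit of CPM in IgG, was at 308% and departs from the share. The lowest of the 132 genes were Alb at 0.567%, Fabp3-ps1 at 0.676%, Timp4 at 1.38% and Hba-a2 at 1.57%. So not all RNA of the IgG library lay in the RIP at that share. The IgG library also held RNA of plasma proteins, with Alb at 204.8 CPM, Ahsg at 95.1 and Afp at 81.2. The test on OXPHOS and fat genes does not cover these, so a single tissue as the source is not shown. Sex-linked genes differed too. Xist stood at 2.05 CPM in the IgG library, 631.1 in the RIP and 599.8 in control islets, and Y genes summed to 59.9, 9.79 and 7.48 CPM. The IgG library thus held mainly RNA of male mice, while the RIP and control islets held much RNA of females. The labels give no tissue but islets, so no biological explanation was tested, and whether the RNA entered before or after the immunoprecipitation stays open.

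Lymphocyte genes were lower in the library labelled knockout than in control islets. The immune list median was between -1.59 and -1.52 under all 4 scalings, which differ too little for this pair (by 0.0746 log2 units at most) to test the choice of scaling. Fewer leukocytes of every type, and any scaling alone, are argued against by the macrophage list, whose median was 2.15 log2 units above that of the B cell list, with the lower quartile of macrophage genes (-0.68) above the upper quartile of B cell genes (-2.09). Lymph node tissue carried over with the control islets is a candidate explanation, since lymph node stroma genes had a median of -2.82 over 7 genes (interquartile range -3.44 to -0.26), with Cxcl13, at 134.8 CPM in control islets, not called. The RIP, from wild-type islets, was low in these genes too. B cell genes summed to 1539 CPM in control islets, 290 in the labelled knockout and 254 in the RIP. T cell genes summed to 395, 55.2 and 29.7. A low level was thus not particular to the labelled knockout, though the RIP may also select RNA. Genotype and lymphocytes within the islets of the control mice stay open and untested, with 1 library per group and Igf2bp2 not lower in the labelled knockout.

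Many genes that control islets express were at 0 in the RIP. Sampling at the depth of the library is argued against, since 18.7% of 2015 genes at 5 to 10 CPM in control islets were at 0 in the RIP and 0.298% in the labelled knockout thinned to the RIP total. A candidate explanation is few starting molecules that were each read many times, since 5.94% of 15380 detected genes had 1 to 5 counts, against 23.9% of 21032 genes in the thinned control. Selection by IMP2 was not tested on these genes and stays open, and counting intervals on reads are then too narrow for the RIP.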

How the results depend on the processing

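Both islet libraries as denominator, molecule intervals and leaving out immune genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Of 69 alternative values of the main results 54 held, of 192 values of named genes 153 held, and of 412 list medians 370 held. The number of genes higher or lower in the labelled knockout was 495 and 1585 at a minimum of 5 CPM and 196 and 1377 at 2-fold, where fewer genes can pass, and 264 and 1586 with an assumed variation of 0.2, which widens each interval. Genes higher in RIP over IgG numbered 3951 at a minimum of 5 CPM, 2723 over control islets, 2652 over both islet libraries and 2315 with molecule intervals. Genes lower numbered 2805 under totals without acinar and hormone genes and 2822 with molecule intervals. The genes lower in the labelled knockout had a median RIP ratio of 0.64 at a minimum of 5 CPM, 2.03 at the 2-fold limit and -1.02 over both islet libraries, each standing apart from random lists, and the cause was not tested. The last ratio shares the islet libraries with the call. Unchanged simulated libraries gave 0.03, but they hold no true difference between the islet libraries. They therefore cannot show how much of -1.02 comes from sharing them. Over control islets in place of IgG, lists that stood apart over IgG stood apart the other way for immune (-2.01), B cell (-2.95), immediate early (-0.59), Schwann, adipocyte and blood (1.36), OXPHOS (1.15) and brown adipocyte genes (5.53). The sign changed and the list no longer stood apart for delta, PP and epsilon cell (-0.63), acinar (-0.45), ductal (-0.17), hypoxia (0.0935) and sex-linked genes (0.88). Sez6l (-0.0103, -0.15 to 0.13) and Pdx1 (-0.38) changed sign too, Sez6l with an interval across 0 and Pdx1 with one across 1-fold on molecules (0.468 to 1.19). The cause was not tested. Lists that stood apart over control islets but not over IgG, with the opposite sign, were T cell (-5.60), S and G2/M (-1.09), lymph node stroma (-1.37), macrophage (-1.06) and target and paralogs (2.13). Igf2bp2 (1.97) and Igf2bp3 (2.13) also changed sign. That denominator also made 24 named genes move, 6 lists weaker and 9 stronger. The mean of small noncoding RNA in the labelled knockout was -0.11 against a median of 0.39, with 1 member called higher and 2 lower. At an estimated 18 reads per molecule, a gene at 0 in the RIP is not bounded at 3 reads.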

Other observations

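The clock genes and the 53 genes below were chosen only after the values were seen, while the tests on 3' UTRs were fixed before.

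Evening-phase genes of the circadian clock were shifted upward in the library labelled knockout. Of 10, 6 were called higher, with a median log2 ratio of 0.65 that lay above all 10000 random lists. Dbp, a clock output transcription factor, stood at 30.3 CPM in control islets and 65.4 in the labelled knockout, Per2 at 29.1 and 62.5, and Per3 at 15.3 and 42.6. The morning-phase genes Arntl (Bmal1), at 13.2 and 5.19 CPM, and Nfil3, at 24.7 and 8.69 CPM, were called lower, and the 4 measured genes of that list had a median of -0.72 (percentile 3.02), which did not stand apart. The hour of islet collection was not given in the sources used here.

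Igf2bp1, the paralog scarce in both islet libraries, was abundant in the RIP, with 122.1 CPM against 39.6 in the IgG library, 0.342 in control islets and 1.32 in the labelled knockout. On molecule intervals, 53 genes, 36 of them protein-coding, lay above 2-fold over both the summed islet libraries and the IgG library. They include Pabpc4, a cytoplasmic poly(A)-binding protein, at 13.9-fold over islets (12.1 to 15.9) and 3.28-fold over IgG, and Larp4b, an RNA-binding protein that stabilizes mRNA, at 4.28-fold over islets (3.69 to 4.94). Others were the chromatin genes Bptf at 4.67-fold (3.94 to 5.50) and Chd7 at 4.04-fold, the adhesion gene Cadm1 at 4.80-fold, and Phactr1 at 4.09-fold (3.58 to 4.65). Of the 53 genes, 51 were measured in labelled knockout over control, with a median log2 ratio of 0.29 that lay above all random lists, whose median was 0.01. The islet lists were shifted by similar amounts, so the value is not shown to be particular to RNAs recovered with IMP2.

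IMP2 binds 3' UTRs and is reported to prefer CATH motifs (CAT followed by A, C or T), so RNAs recovered with it were predicted to have longer 3' UTRs and denser motifs, each with a rank correlation above 0.1. Neither prediction held for RIP over control islets across 11076 genes, which are not independent replicates. After expression, transcript length and GC content were removed, the Spearman correlation with 3' UTR length was 0.0745 (0.0568 to 0.0938), from 0.0072 before. It was 0.0820 (0.0618 to 0.1012, which reaches past 0.1) over 9536 genes. That run left out genes whose RIP level could owe 20% or more to RNA shared with the IgG library. The intervals come from 1000 resamplings of the genes and measure spread over genes, not counting error. With 3' UTR length removed as well, the correlation with motif density was -0.0151 (-0.0330 to 0.0042), and -0.0196 (-0.0386 to -0.0003) without those genes. Genes entered from a mean of 5 CPM, on ratios of reads, with the 3' UTR of the longest coding transcript. Both choices can weaken a correlation. A miss of 0.1 therefore does not show that recovery with IMP2 is unrelated to these features.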
